A study of Mus musculus with 2 samples.

How the data were processed

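Total RNA of primary mouse osteoblasts was measured on 2 Affymetrix mouse arrays, 1 for cells in MDA-PCa2b medium and 1 for cells in PC-3 medium. Per the labels, the culture medium was alpha-MEM containing fetal calf serum at 10%; cells were differentiated for 10 days with ascorbic acid (50 µg/ml) and beta-glycerophosphate (10 mM), and treated for 6 hours after overnight serum starvation. RNA was extracted with TRIzol, purified on RNeasy columns, and 5 µg was used for biotin-labelled cRNA. Groups were taken from the source description of each sample; the title of the PC-3 sample also carries the prefix of the other line's name.

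The deposited values are probe set signals, that is intensity on a linear scale, which the authors made with GCOS 1.4 and MAS5, per the submitters' processing notes. The values themselves showed that both arrays had been scaled globally: the mean over probe sets without the lowest and highest 2% was 299.9 on each. The scaling target, detection calls and background settings were not given in the sources used here, so no call of presence was used. Of 45101 probe sets 64 were controls, which left 45037, and 0 columns of per-sample values were left out. The number of arrays limits the precision: with 1 array per group no SD, standard error or p-value between the media could be computed.

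Probe sets were named through the platform annotation, in which 34958 probe sets had 1 gene, 932 several and 9211 of all 45101, controls included, were not listed; none was named from an entry with several genes. Of the named probe sets 34754 were matched by Entrez identifier to a table of mouse genes (assembly GRCm38.p6, used for names alone), and 0 symbols were updated by it. Older names in the gene lists were matched to current symbols only where the older name belonged to no other gene. No coordinates were used.

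The following choices were made before the data were examined. Signals below the 50th percentile of their array (56.7 with MDA-PCa2b medium and 57.7 with PC-3 medium) were set to that floor, and log2 was taken. The ratio of a gene was the log2 signal with PC-3 medium minus that with MDA-PCa2b medium. The probe set with the highest mean signal stood for its gene. Where 1 array was at the floor the ratio was given as a bound, and where both were it was not given. The scatter between probe sets was the SD of log2 ratios around the mean of their gene, over genes with several measured probe sets.

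The named genes were the 12 highest and 12 lowest ratios among genes above the floor on both arrays whose higher signal was above the 75th percentile of its array, and the 5 largest bounds in each direction. Within each list the measured members that differed at least 2-fold were named, at most the 4 largest, or the 2 largest where none did. Members of small counts outside this rule (Socs2, Myc, Lif in the cAMP and PTH list, Sema3a and Vdr among osteoclast-regulating factors) and genes said to be so were chosen after their values were seen. Other probe sets that went the opposite way by at least 1.5-fold were given beside the gene.

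The 32 gene lists were chemokines; interleukins and inflammatory cytokines; and response genes of STAT3 and STAT5, NF-kB, BMP, TGF-beta, cAMP and PTH, interferon, and retinoid, vitamin D and glucocorticoid. Further lists held immediate-early, MAPK feedback and EGF-family, osteoblast, osteocyte, osteoclast-regulating, Wnt, hypoxia and glycolysis, ATF4 and unfolded protein response, sterol and fatty acid synthesis, oxidative stress and metal response, cell cycle, matrix, matrix protease, and angiogenic and growth factor genes. Marker lists covered macrophages and osteoclasts, endothelium, adipocytes, chondrocytes, skeletal muscle, fibroblasts and pericytes, and lymphocytes and other blood cells, and ribosomal protein and reference genes served as lists with no direction foreseen. The median log2 ratio of each list's measured members was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list was said to stand apart below a percentile of 2.5 or above 97.5. The percentile describes these arrays and is no p-value, since genes are not replicates.

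The alternatives were floors at the 25th and 75th percentiles, log2(signal + 16) with no floor, quantile normalisation, the median log2 ratio set to 0, the mean over a gene's measured probe sets, leaving out probe sets that can match several transcripts, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Scripts were tested on simulated data for this comparison. Of 100 genes changed by 1.5 log2 units 98% were found at least 2-fold different in the right direction, and of 100 changed by 2.5 log2 units 100%, against 0% of 10672 unchanged genes. Of 200 unchanged lists 4% stood apart, and of 50 lists raised by 0.3 log2 units 100%. The simulated scatter was normal and of the probe set SD at every signal, with no spread between cultures. Changed genes were drawn from the brighter ones, and lists were drawn at random. These rates therefore test the scripts and are not error rates of the 2 arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.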

Results

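The study asked how factors released by different prostate cancer cell lines act on the transcripts of bone-forming cells. Primary mouse osteoblasts at day 10 of differentiation were starved of serum overnight and then held for 6 hours in medium conditioned by MDA-PCa2b or PC-3 cells. Both lines are human prostate cancer lines from bone metastases: MDA-PCa2b is known for bone-forming lesions and PC-3 for bone-destroying ones. RNA of each culture was hybridised to 1 Affymetrix mouse array with 45101 probe sets. There were no replicates, so differences could be set only against the scatter between probe sets of the same gene, and no test between the media was possible. An array of osteoblasts without tumour-cell medium was not analysed here, so "higher" and "lower" below always describe PC-3 medium relative to MDA-PCa2b medium.

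Both arrays had a trimmed mean signal of 299.9. Signals ranged from 0.0447 to 24832 with MDA-PCa2b medium and from 0.105 to 24562 with PC-3 medium. The 18 bacterial spike-in probe sets had a median log2 ratio of 0.03 (SD 0.08). The 3'/5' signal ratio of beta-actin was 1.399 with MDA-PCa2b medium and 1.504 with PC-3 medium, and that of Gapdh was 0.73 and 0.72. Of 18193 genes with a probe set, 10649 were above the floor on both arrays, 327 with PC-3 medium alone, 359 with MDA-PCa2b medium alone and 6858 on neither array.

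Among genes above the floor on both arrays, the highest ratios with PC-3 medium were those of several chemokine genes, the metallothionein genes Mt1 and Mt2, and the genes Saa3 and Chil1. Cxcl5, which attracts neutrophils, gave a signal of 140 with MDA-PCa2b medium and 6418 with PC-3 medium, 45.8-fold higher. The metallothionein genes Mt2 and Mt1, whose products bind zinc and copper, were 26.6-fold and 12.5-fold higher. Saa3, an acute-phase serum amyloid gene, was 24.8-fold higher (306 and 7587), and Chil1, which encodes a secreted chitinase-like glycoprotein, 24.7-fold higher. The Chil1 signal of 69.3 with MDA-PCa2b medium was close to the floor. Its log2 ratio of 4.62 was 2.51 with the floor at the 75th percentile. Cxcl1, another neutrophil chemokine gene, was 23.5-fold higher, with log2 ratios of 1.77 and 5.29 by its other probe sets, against 4.55 by the brightest. The monocyte chemokine gene Ccl2 was 14.3-fold higher.

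The remaining genes with the largest positive ratios were Cxcl9, an interferon-induced T-cell chemokine gene (12.3-fold), Gbp2, an interferon-induced GTPase gene (10.2-fold), the metalloreductase gene Steap4 (10.1-fold), the tissue transglutaminase gene Tgm2 (8.67-fold) and Gfra1, the gene of a GDNF co-receptor (8.33-fold). Other probe sets gave smaller log2 ratios for Cxcl9 (2.52 against 3.62) and Gfra1 (1.70 and 2.56 against 3.06). Both genes had signals not far above the floor with MDA-PCa2b medium (72.5 and 92.8), so the size of their ratios is uncertain. Some genes were above the floor with PC-3 medium alone, so their ratios are bounds. Prg4, which encodes the joint lubricant lubricin, was at least 61.3-fold higher, with a signal of 3474 in PC-3 medium. Ccl7, a monocyte chemokine gene, was at least 16.2-fold higher, and the protease inhibitor gene Serpina3n at least 12.9-fold higher. Zc3h12a, which encodes an RNase that degrades cytokine transcripts, was at least 10.6-fold higher, although its second probe set gave a log2 ratio of 0.83. Mmp3, the stromelysin-1 gene, was at least 9.25-fold higher.

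The gene with the lowest ratio was Smpd3, the neutral sphingomyelinase gene needed for bone mineralisation, with signals of 1432 in MDA-PCa2b medium and 69.8 in PC-3 medium (20.5-fold lower). Its other probe sets gave log2 ratios of -3.68 and -2.27. Slc8a3, a sodium-calcium exchanger gene, was 11.2-fold lower (log2 ratios of -3.49 and, by its second probe set, -2.55), and Cdo1, the cysteine dioxygenase gene, 6.75-fold lower. Ifitm5, an osteoblast-restricted membrane protein gene, was 6.00-fold lower (4442 and 741). Bambi, which encodes a pseudoreceptor that blocks TGF-beta family signals, was 5.28-fold lower, and Sgms2, a sphingomyelin synthase gene, 4.80-fold lower.

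Tmtc2 was 5.76-fold lower by its brightest probe set, but its other probe set gave a log2 ratio of only -0.35. The long non-coding RNA Rian was 6.30-fold lower by its brightest probe set, but its other 3 probe sets disagreed, with log2 ratios from -1.399 to 0.71. Lower signals were also given by Rerg (4.67-fold), the RNA-binding protein gene Raly (4.39-fold), the dynein intermediate chain gene Dync1i1 (4.26-fold) and the receptor tyrosine phosphatase gene Ptprz1 (4.19-fold). Genes above the floor with MDA-PCa2b medium alone were led by Car8 (at least 6.35-fold lower), the metalloprotease gene Adamts18 (5.14-fold), Rhpn2 (5.02-fold), the Wnt inhibitor gene Dkk1 (4.40-fold) and Ranbp3l (3.78-fold), all of them bounds. The second probe set of Dkk1 gave -0.31 and that of Rhpn2 -0.47 on the log2 scale, and the other probe sets of Adamts18 gave -0.86 and -0.61.

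Of the genes above the floor on both arrays, 202 were at least 2-fold higher and 179 at least 2-fold lower, which made 53.0% of these genes higher (58.0% with the median log2 ratio set to 0). At a threshold of 1.5-fold the balance was the other way, with 552 genes higher and 663 lower. The 2-fold counts depended on the floor: they were 90 and 56 with the floor at the 75th percentile and 527 and 436 with log2(signal + 16) and no floor. A further 38 genes were at least 2-fold higher and 31 at least 2-fold lower as bounds. Most genes differed little: 88.6% lay within 1.5-fold, the median log2 ratio was -0.04 and the SD over genes 0.44. Among the genes at least 2-fold higher, 99 had a second measured probe set, which was also higher for 97; among those at least 2-fold lower, it was also lower for 90 of 93. Log2 ratios of different probe sets of the same gene scattered with an SD of 0.24 (4924 genes), from 0.31 in the lowest tertile of signal to 0.14 in the highest. This is measurement scatter within a single pair of arrays and not the spread between cultures.

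**Figure D1:**
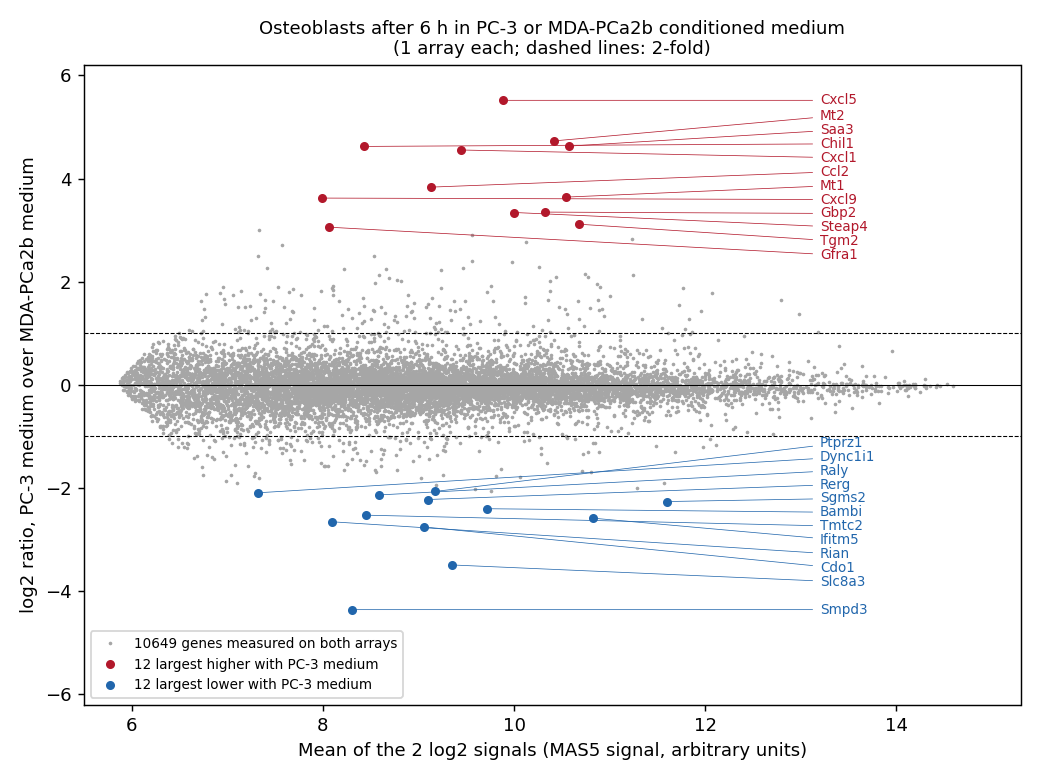
Each point is 1 of the 10649 genes above the floor on both arrays, with the mean of its log2 signals (MAS5 signal, arbitrary units) on the x axis and its log2 ratio, PC-3 over MDA-PCa2b medium, on the y axis. The 12 named genes with the highest ratios (red), led by Cxcl5 at 5.52, and the 12 with the lowest (blue), led by Smpd3 at -4.36, lie outside the dashed 2-fold lines.

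Chemokine genes were higher as a group: 10 of 21 measured members were at least 2-fold higher and none at least 2-fold lower. They were led by Cxcl5, Cxcl1, Ccl7 and Ccl2, and the median log2 ratio was 0.90, above those of all 10000 random lists of like size and signal. Among 14 measured interleukin and cytokine genes, 3 were at least 2-fold higher: Il6, a driver of acute-phase responses (3.48-fold), the alarmin gene Il33 (2.72-fold) and Lif, a cytokine gene of the Il6 family (2.10-fold). The median of this list was 0.42 (percentile 99.99).

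NF-kB response genes had the highest median of the 32 lists, 1.64, with 16 of 22 measured members at least 2-fold higher and none lower. Map3k8, a kinase gene of the pathway, was at least 6.26-fold higher, and Nfkbiz, which encodes a nuclear inhibitor-like cofactor, 5.24-fold higher, beside Zc3h12a and Gbp2. STAT3 and STAT5 response genes had a median of 1.03, and 14 of 27 were at least 2-fold higher. They were led by Saa3, Serpina3n, Steap4 and the siderophore-binding protein gene Lcn2 (at least 8.45-fold). The members at least 2-fold lower were Socs2, a feedback inhibitor gene of STAT5 signalling (2.16-fold), and the transcription factor gene Myc (2.06-fold). Interferon response genes had a median of 0.44, with 6 of 28 at least 2-fold higher, among them Gbp2, the antiviral gene Oasl2 (3.51-fold), Gbp3 (3.34-fold) and the immunoproteasome gene Psmb8 (2.83-fold). All 3 medians lay above those of all 10000 random lists. With the floor at the 75th percentile the NF-kB median was 0.99, below the 1.31 of chemokines, and with log2(signal + 16) the chemokine median was 0.46.

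Macrophage and osteoclast markers, measured beside these inflammatory lists, had a median of only 0.10 over 25 genes (percentile 98.5), and none differed 2-fold. The largest ratios were those of Fcgr1, an Fc receptor gene (log2 ratio 0.82, second probe set -0.02), and of the lysosomal gene Cd68 (0.59). This list no longer stood apart with the floor at the 25th percentile (97.18) or the 75th percentile (94.5). Averaging probe sets gave a percentile of 96.81, and random lists not matched on signal gave 97.345.

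Immediate-early genes split into opposite groups. Junb (3.79-fold), Fosl1 (3.39-fold, second probe set 0.26 on the log2 scale) and Ier3 (3.13-fold) were higher, while the nuclear receptor gene Nr4a3 was at least 3.004-fold lower. Of 28 measured members 4 were at least 2-fold higher and 7 at least 2-fold lower; the median was 0.10 (percentile 98.3) but the mean was -0.03. The cAMP and PTH response list, which shares the lower genes Nr4a1, Nr4a2 and Nr4a3 with this list, had a median of 0.06, a mean of -0.12 and a percentile of 90.6, which did not stand apart. Of its 22 measured members 2 were at least 2-fold higher, Il6 and Lif, and 5 lower, including Nr4a3, its relative Nr4a1 (2.89-fold) and the phosphodiesterase gene Pde10a (2.94-fold by its brightest probe set, -0.29 to 0.02 by its others). MAPK feedback and EGF-family genes had a median of 0.14 over 19 genes, with Ier3 and Phlda1 (2.68-fold) higher. Their percentile of 96.95 did not stand apart. It did with the floor at the 25th (99.16) or 75th percentile (99.89), with log2(signal + 16) (98.63) and against random lists not matched on signal (98.37).

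Of 23 measured osteoblast differentiation and mineralisation genes, 6 were at least 2-fold lower and none higher. They were led by Smpd3, Ifitm5, the carbonic anhydrase gene Car3 (4.01-fold) and Tnfrsf11b, the gene of the RANKL decoy receptor osteoprotegerin (2.96-fold). Col1a1, the main collagen gene of bone, had signals of 20109 and 20052, and Sparc, the osteonectin gene, 24832 and 24562; both are close to the top of the signal scale, where differences can be compressed. The matrix protein gene Omd had signals of 9332 and 4794 (log2 ratio -0.96), and another probe set of the collagen gene Col1a2 gave -0.59 where its brightest gave -0.02. These genes were chosen after their values were seen. The list's median was -0.12 (mean -0.66), with a percentile of 6.54 that did not stand apart; averaging over probe sets gave a percentile of 0.035.

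Osteocyte genes included 5 of 15 measured members at least 2-fold lower and none higher. These were led by Dkk1, Ptprz1, Dmp1, a mineral-binding matrix protein gene (4.14-fold), and Tnfrsf11b. The median was -0.10 (percentile 23.4). With the floor at the 25th percentile the list stood apart, at a percentile of 0.1 and a median of -0.30 over 16 genes. Genes for factors that regulate osteoclasts were higher as a group, with a median of 0.41 over 21 genes, above all random lists. This median was 0.20 with probe sets averaged and 0.22 with the floor at the 75th percentile. The list holds inhibitors of osteoclasts such as Tnfrsf11b beside inducers, so its median gives no direction of osteoclast regulation. In this list 6 members were at least 2-fold higher, led by Ccl2, Il6 and the chemokine gene Ccl5 (3.21-fold), and 3 at least 2-fold lower: Tnfrsf11b, the semaphorin gene Sema3a (2.09-fold) and the vitamin D receptor gene Vdr (2.09-fold). Tnfsf11, which encodes the osteoclast-inducing ligand RANKL and was chosen after its values were seen, had signals of 453 and 818, 1.81-fold higher. Of the 21 measured genes, 14 also belonged to another list, so the lists are not independent of each other.

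The BMP and Wnt lists had low medians, with members on both sides of 0. Of 26 measured BMP response genes 7 were at least 2-fold lower and none higher, with a median of -0.26 (percentile 0.06). They were led by Bambi, Id3, a direct BMP target gene (3.21-fold), and the transcription factor genes Dlx3 (at least 2.69-fold) and Hey1 (at least 2.57-fold). Of 30 measured Wnt targets and antagonists 6 were at least 2-fold lower and 2 higher, with a median of -0.38, below those of all random lists. Several of these genes encode Wnt inhibitors rather than effectors: Dkk1 and Apcdd1 (3.37-fold by its brightest probe set, log2 ratios of -1.42 to -0.22 by its others) were lower, and the secreted antagonist gene Sfrp4 was 3.80-fold higher.

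TGF-beta response genes had a median of 0.16 over 26 genes (percentile 99.99). In this list 2 were at least 2-fold higher, the matrix protein gene Tgfbi (7.14-fold) and the repressor gene Tgif1 (2.10-fold), and none lower. Fibrillar and basement membrane matrix genes had a median of 0.06 over 32 genes and none differed 2-fold; the largest ratios were 0.97 for the laminin gene Lamb1 and 0.95 for the fibulin gene Fbln2, whose second probe set gave 0.08. Their percentile of 99.71 no longer stood apart against random lists not matched on signal (94.64). Matrix proteases and their inhibitors had a median of 0.18 (percentile 99.99), with 4 of 25 at least 2-fold higher: Mmp3, the aggrecanase gene Adamts5 (3.02-fold), Mmp19 (2.07-fold) and the inhibitor gene Timp1 (2.04-fold).

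Cell cycle genes had a median of -0.49, below those of all random lists. Of 37 measured genes 2 were at least 2-fold lower, none was higher and 35 lay between, although 36 had a log2 ratio below 0. The replication licensing gene Cdc6 was 3.41-fold lower and the cyclin gene Ccne2 2.53-fold lower. Genes of sterol and fatty acid synthesis had a median of -0.46, also below all random lists; 2 of 29 were at least 2-fold lower and 1 higher, and 26 had a log2 ratio below 0. Dhcr7, which encodes the last enzyme of cholesterol synthesis, was 2.58-fold lower and the isomerase gene Idi1 2.01-fold lower, while the mevalonate pathway kinase gene Pmvk was 2.04-fold higher.

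Hypoxia and glycolysis genes had a median of 0.28 over 31 genes, above all random lists. The members at least 2-fold higher were Egln3, an oxygen-sensing hydroxylase gene (3.01-fold), the vasoactive peptide gene Adm (2.88-fold), the glycolytic regulator gene Pfkfb3 (2.67-fold) and the mitophagy gene Bnip3 (2.04-fold). Oxidative stress and metal response genes had a median of 0.13 over 21 genes (percentile 99.5). Besides Mt1 and Mt2, the glutathione reductase gene Gsr (5.29-fold) and the haem oxygenase gene Hmox1 (2.71-fold) were at least 2-fold higher. ATF4 and unfolded protein response genes had a median of 0.06, a mean of -0.02 and a percentile of 97.25 over 34 genes, which did not stand apart. The transcription factor gene Cebpb was 4.06-fold higher, the stress sensor gene Sesn2 2.41-fold lower by its brightest probe set (-0.22 by the other), and Vldlr 2.18-fold lower.

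Angiogenic and growth factor genes had a median of 0.03 over 28 genes (percentile 90.1), with Angptl4, a lipoprotein lipase inhibitor gene, 4.39-fold higher and the growth factor gene Pdgfa 2.19-fold lower; averaging over probe sets gave a percentile of 98.63. Retinoid, vitamin D and glucocorticoid response genes had a median of 0.17 over 17 genes (percentile 99.3). Here Mt2, the retinoic acid binding protein gene Crabp2 (3.93-fold) and the scavenging chemokine receptor gene Ackr3 (3.10-fold) were among the 4 at least 2-fold higher, and Vdr was lower. Without probe sets that can match several transcripts this list no longer stood apart (92.11).

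Markers of other cell types mostly showed small differences. Fibroblast and pericyte markers had a median of 0.43 over 14 genes, above all random lists, with Cd34, a surface marker gene of stromal and vascular progenitors, 2.30-fold higher. Chondrocyte markers had a median of -0.21 over 19 genes (percentile 1.51) but a mean of 0.04. Prg4, with its bound of 5.94, was the only member at least 2-fold higher, and the hypertrophic cartilage collagen gene Col10a1 was 2.62-fold lower. With the floor at the 75th percentile the chondrocyte list no longer stood apart (16.84). Adipocyte markers had a median of 0.14 over 12 genes (percentile 93.2), led by the fatty acid binding protein gene Fabp4 (log2 ratio 0.98) and the adiponectin gene Adipoq (0.47); averaging over probe sets gave a percentile of 98.69. Endothelial markers were measured for only 4 of 20 genes, with a median of 0.18 (percentile 83.8) and Ecscr 3.41-fold higher.

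Skeletal muscle markers were measured for 5 of 22 genes, with a median of 0.00 (percentile 46.9), a log2 ratio of -0.17 for the myosin light chain gene Myl4 and a bound of 0.12 for the desmin gene Des. The value of Des depended on the floor: it was 2.13 with the floor at the 25th percentile and 1.56 with log2(signal + 16). Lymphocyte and haematopoietic markers were measured for 3 of 23 genes, with a median of -0.23 (percentile 10.1), a bound of -0.32 for the T-cell gene Cd8a and a log2 ratio of -0.23 for the leukocyte gene Ptprc. The sign of this median turned to 0.10 with the floor at the 25th percentile and to 0.19 with log2(signal + 16). Ribosomal protein genes had a median of -0.03 over 22 genes (percentile 68.0), which was 0.01 with the median of all genes set to 0; the lowest ratios were those of Rpl14 (-0.40) and Rpl37 (-0.14). Reference genes had a median of -0.05 over 13 genes (percentile 47.9). In that list Hprt gave -0.22 and Ywhaz -0.20, the latter 0.12 when its probe sets were averaged and 0.31 without probe sets that can match several transcripts. In all, 20 of the 32 lists stood apart, as a description of these 2 arrays.

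**Figure D2:**
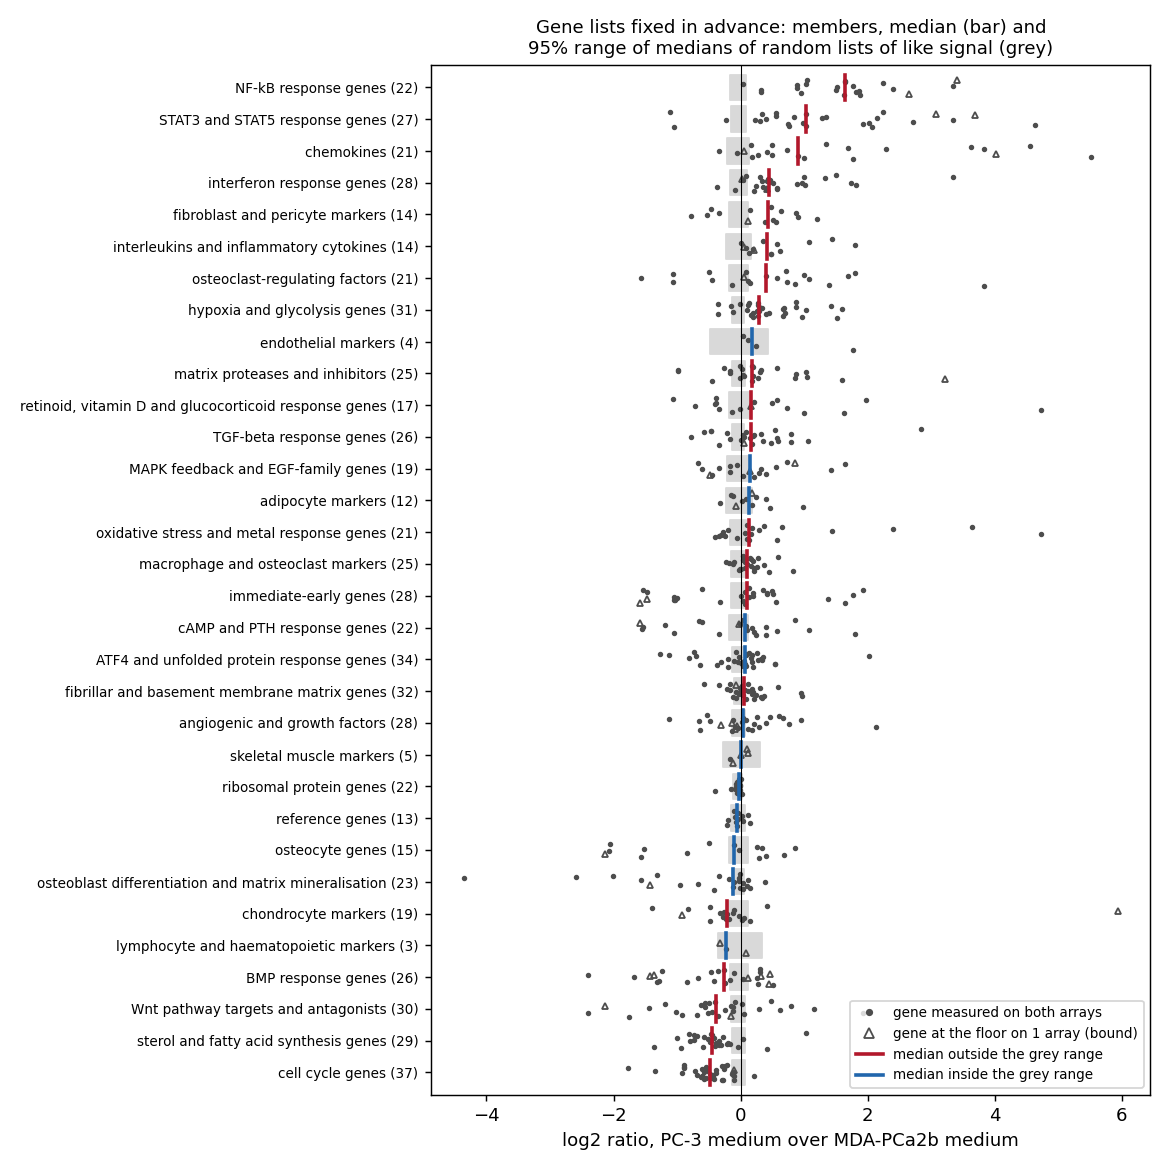
Each row is 1 of the 32 gene lists, with the number of measured genes in brackets; points are log2 ratios of its genes, PC-3 over MDA-PCa2b medium (triangles: bounds), the vertical bar is the median (red if outside the grey range) and the grey band holds 95% of the medians of 10000 random lists of like signal. NF-kB response genes have the highest median, 1.64, and cell cycle genes the lowest, -0.49.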

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

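The tests of macrophage number, of cell loss and of BMP signalling, and that of cultures differing for reasons other than the medium, were chosen after the results were seen; those of probe sets matching several transcripts and of single probe set scatter were fixed before.

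Probe sets without a single gene name took no part in the comparison of genes. Of these, 48 were at least 2-fold higher with PC-3 medium and 25 at least 2-fold lower, among 2611 above the floor on both arrays. The largest difference was that of a probe set with signals of 64.7 in MDA-PCa2b medium and 857 in PC-3 medium.

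The inflammatory lists were higher with PC-3 medium. A higher number of macrophages in that culture is argued against as the source for the STAT and NF-kB lists. Their medians lay at least 0.93 above the 0.10 of macrophage markers (0.78 or more under every alternative). The same marker median served all lists, so the calls differ only through the lists' own medians. The markers bear on macrophage number alone, and a change within macrophages present in both cultures was not tested. More macrophages stay open for chemokines, with a gap of 0.80 that was 0.36 with log2(signal + 16). They stay open for the cytokine and interferon lists too, where the smaller gap was 0.32, and 0.19 with log2(signal + 16). Probe sets that match several transcripts stood for few members of the NF-kB list, such as Nfkbie, Tnfaip2 and Nfkbib. The list's median was 1.52 without such probe sets, so it does not rest on them. With so few left out the median could hardly have fallen far, so this check excludes little more. Scatter of single probe sets is argued against because, of 43 members of the chemokine, cytokine, STAT and NF-kB lists at least 2-fold higher, 20 had a second measured probe set, which was higher too in 100% of them. A difference between the cultures other than the medium cannot be told apart from an effect of the medium with 1 array per group, and the base medium of each cancer line, not given in the sources used here, is part of this.

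A subset of osteoblast and osteocyte genes was lower with PC-3 medium. Fewer osteoblasts as the cause stay open. Of the 28 members of both lists with signals under 10000, 15 lay above a 2-fold lower ratio by more than 2 probe set SDs. Among them were Alpl (-0.41), Pth1r (-0.35) and Phex (-0.10), but also Atf4 (0.10) and Hyou1 (0.25). Members that other cells express as well would not fall with a loss of osteoblasts, so the count cannot decide. Fibroblast and pericyte markers had a median of 0.43. A loss of the most mature cells alone stays open too. The osteocyte list's median was -0.10, and with the floor at the 25th percentile -0.30 over 16 genes, at percentile 0.1. Neither median was 2-fold lower. Lower BMP signalling is a candidate explanation without independent support. The 22 members of the BMP list outside both lists had a median of -0.21 and a percentile of 1.02. They are part of a list already seen to be low. Some are genes of BMP ligands or antagonists, such as Bmp4 and Nog, rather than responding genes. Their low median may equally follow from another difference between the cultures, which the design does not separate.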

How the results depend on the processing

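All tests here were planned. Quantile normalisation and setting the median log2 ratio to 0 moved no list median or named gene by more than the probe set SD and no count by over 1.5 times; the former turned the muscle median from 0.00 to -0.03, the latter the ribosomal median from -0.03 to 0.01. With the floor at the 25th percentile the counts at least 2-fold higher and lower were 426 and 382 (bounds 258 and 207), because more dim genes entered; the medians were 0.65 for chemokines and 0.10 for lymphocyte markers (below 0 in the report), and the percentiles 99.16 for MAPK genes, 0.1 for osteocyte genes and 97.18 for macrophage markers. With the floor at the 75th percentile the counts were 90 and 56 (61.6% higher), the probe set SD 0.16, the medians 1.31 for chemokines, 0.99 for NF-kB and 0.47 for MAPK genes, and the percentiles 99.89 for MAPK, 94.5 for macrophage and 16.84 for chondrocyte genes; endothelial, muscle and lymphocyte lists gave no value. With log2(signal + 16) the counts were 527 and 436, the SD 0.38, the medians 0.46 for chemokines and 0.19 for lymphocyte markers, and the MAPK percentile 98.63. Averaging probe sets gave percentiles of 0.035 for osteoblast genes, 98.63 for growth factors, 96.81 for macrophage and 98.69 for adipocyte markers. Without probe sets that match several transcripts the retinoid list stood at 92.11. Random lists not matched on signal gave 98.37 for MAPK, 94.64 for matrix and 97.345 for macrophage genes. Thresholds of 1.5-fold gave 552 and 663 (bounds 82 and 81), and of 3-fold 79 and 36 (bounds 17 and 10). Beyond the floors and thresholds, whose construction sets what is counted, the cause was not tested. Of 674 values of 100 named genes 84 moved by more than the probe set SD, and Ywhaz alone changed sign; the higher floor left 21 of these genes without a value and shrank the ratios of dim ones such as Dync1i1 (-0.14), and dropping probe sets left 5. No paired analysis was possible because there was 1 array per group. Ratios of genes near the floor are limited by signal over background, and their size is least certain.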

Other observations

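All genes and tests of this part were chosen after their values were seen. The following single genes, picked for their ratios and standing for no group, were at least 2-fold higher or lower. Tlr2, which encodes a receptor for bacterial lipoproteins, was 4.79-fold higher (signals of 323 and 1549), the interleukin receptor genes Il13ra1 and Il1r1 4.65-fold and 3.68-fold higher, and Irak3, which encodes an inhibitor of Toll-like and interleukin-1 receptor signalling, 2.70-fold higher. Tnfrsf9, a TNF receptor family gene, was 8.06-fold higher from a signal of 56.8, close to the floor (log2 ratios of 3.01 and, by its other probe set, 1.28), and the GTPase gene Gbp6 7.45-fold higher. Of secreted proteins, the lipopolysaccharide binding protein gene Lbp was 3.70-fold higher and the protease inhibitor gene Slpi 2.94-fold higher. The pentraxin gene Ptx3 was 6.83-fold higher by its brightest probe set, although its other probe set gave a log2 ratio of -0.53.

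Smpd3 and Sgms2, which encode enzymes that break down and make sphingomyelin, were both lower, at log2 ratios of -4.36 and -2.26, and so was the sphingosine-1-phosphate exporter gene Spns2 (-1.46). Sphk1, the gene of the kinase that makes sphingosine-1-phosphate, was 3.49-fold higher (0.55 by its second probe set on the log2 scale), and Ugcg, a glucosylceramide synthase gene, 2.27-fold higher. Single genes of membrane transport that were lower, besides Slc8a3, were the potassium channel gene Kcnk1 (4.06-fold), the citrate transporter gene Slc13a5 (3.82-fold), Panx3, an osteoblast pannexin gene (3.74-fold), and, by their brightest probe sets, the chloride channel gene Ano1 (2.99-fold) and Slc26a7 (2.70-fold), whose other probe sets gave log2 ratios of only -0.34 and -0.24. The transcription factor gene Mef2c was 3.46-fold lower and the growth factor receptor gene Fgfr2 2.27-fold lower.

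The metallothionein genes Mt1 and Mt2 were higher with PC-3 medium. Metal ions in the medium stay open: Slc30a1, a zinc exporter gene induced by the same metal-sensing factor, had a log2 ratio of -0.34, but it is a single gene with 1 measured probe set. Glucocorticoid activity stays open too: 5 glucocorticoid-induced genes had a median of -0.017 but went both ways, with Per1 at 0.58 and Sgk1 at 0.50 against Klf9 at -0.41 and Fkbp5 at -0.38 (0.57 by its second probe set). Slc39a14, a zinc importer gene induced by Il6, was 3.30-fold higher, with its other probe sets at log2 ratios of 1.35 to 2.09.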
